A study of Zea mays with 95 samples.

How the data were processed

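RNA abundance was measured in maize (Zea mays) plants that carried an Ht1 transgene or were null segregants, the siblings without it. Plants received northern leaf blight inoculum or a mock treatment and were sampled at 0.5, 3, 6, 12, 24, 48, 72 and 168 h. The sampled tissue is given only as plant. The 95 libraries fell into 32 groups of genotype, treatment and time, of which 31 held 3 libraries and 1 (transgenic, inoculated, 6 h) held 2. Replicate numbers were assigned in accession order, were used to name a library and not to pair samples. Whether libraries with the same number share a factor is not known. The labels do not say whether replicates were separate plants, so the spread behind the p-values may be partly technical. That spread is between libraries of a group, pooled over all 32 groups, and is not that of the compared libraries alone.

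Sequencing was on an Illumina NovaSeq instrument, per the labels' protocols. Salmon and DESeq2 are named, without versions, in the submitters' processing notes; the transcript annotation is not given in the sources used here. The deposited values were TPM, a length-corrected share of a fixed total, for 131140 transcripts, as the values themselves show: each library used summed to between 999984 and 999999.2, whereas the labels speak of counts. TPM keeps no depth, so the depth of each library is unknown and no counting interval was computed. Because TPM values are shares of one total, a rise of abundant transcripts lowers all others. Of the deposited columns, 22 matched no sample and were not used. An exact 0 made up 35.45% of gene by library values and is reported as listed at 0.

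Transcript TPM were summed per gene by the transcript suffix, which gave 39303 genes. None of the gene IDs matched the reference table of gene names (0 matches), and the files do not pair IDs with names. The 27 gene lists fixed in advance therefore matched 0 genes and were not tested, and a row for the transgene was not analysed here. Gene IDs were limited in advance to 2 that rose and 2 that fell. The 4 were taken by the fixed rule (past the threshold, mean of at least 1 TPM, no overlap between inoculated and mock libraries) in order of absolute fitted log2 fold change. The rule had named CPM where TPM was used and had asked for a described gene, which could not be applied without names. Pooling that order over all times and both genotypes was decided after the values were seen.

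The test fixed before the data were examined was a count model. It needs counts, so limma was used on log2(TPM + 1) in its place, as the fixed design allowed for. Genes at 1 TPM or more in at least 3 libraries were kept (25673 genes), a filter set once the unit was known, in place of a planned count filter. One model with a mean per group was fitted to all 95 libraries (63 residual degrees of freedom), with moderated variances that followed a mean trend, and p-values were adjusted by the Benjamini-Hochberg method within each of 26 contrasts at a threshold of 0.05. The contrasts were inoculated against mock per genotype and time, the difference of these responses between genotypes per time, and transgenic against null plants averaged over the times within each treatment. A fold change is on the log2(TPM + 1) scale and understates the change of low genes. The limma tests were two-sided, and the exchanges of labels and the permutation of ID order counted only values as large or larger. Where a contrast called 0 genes, the number with an unadjusted p under 0.05 is given. Chance alone would give such a p-value to a share of 0.05 of the 25673 genes. A number near or below that share is no sign of a hidden response. R 4.3.3, limma 3.58.1, data.table version 1.17.8, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.

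The model was tested on simulated values with the means and spreads of the 25673 genes. For the 24 h response of null plants it recovered 67 of 100 genes changed 2-fold and 92 of 100 changed 4-fold, with 8 false calls. For the 24 h difference between genotypes it recovered 30 of 100 and 79 of 100, with 4 false calls. For the genotype contrast in mock plants it recovered 100 of 100 at both sizes, with 5 false calls. Changed genes were drawn from those with a mean of at least 2 on the log2(TPM + 1) scale, and every simulated group had the same spread per gene. Values were drawn independently for each gene and library, so no variation was shared by the genes of a library. The false calls therefore cannot show how many arise in the real libraries.

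Alternatives fixed at the same stage as that test were no low-value filter, a fit to the libraries of 1 time or 1 treatment only, and leaving out each library in turn (each replicate number in turn for the averages over times). Alternatives chosen after seeing the data were pseudocounts of 0.1 and 5 TPM and a median-ratio scaling, which divided each library by its median ratio to the geometric mean over genes at 5 TPM or more in every library. A second count model and another count normalization were also fixed and were not run, since they need counts.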

Results

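The series addressed how maize plants with the resistance gene Ht1, which its title describes as encoding an NLR immune receptor, respond to northern leaf blight. Gene expression was compared between inoculated and mock plants of a transgenic and a null genotype at 8 times from 0.5 to 168 h, in 95 libraries. Between 18955 and 21760 genes reached 1 TPM in a library, and the 50 most abundant genes held 15.7% to 35.0% of the TPM. The mean correlation of a library with its group mates ranged from 0.927 to 0.986, and for 73 of 95 libraries the closest library belonged to the same group. Sequencing depth is unknown, since TPM keeps none.

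The first principal component, with 32.6% of the variance, separated times of sampling. Mock null plants lay at 51.1 ± 5.8 (SD, n = 3) at 24 h and at -84.9 ± 15 (SD, n = 3) at 48 h. Inoculated plants at 0.5 h lay at -76.5 ± 7.2 in the null and -82.3 ± 8.5 in the transgenic genotype (SD, n = 3 each), against 12.4 ± 3.5 and -27.5 ± 6.2 in their mocks. At 168 h inoculated plants lay at -21.8 ± 17 in the null and 33.8 ± 7.0 in the transgenic genotype, against -87.3 ± 20 and -96.7 ± 17 in their mocks. The second component, with 18.7%, set the inoculated plants of 168 h apart, at 141 ± 14 in null and 187 ± 21 in transgenic plants (SD, n = 3 each). One inoculated transgenic library at 48 h, replicate 1, lay at -29.86 on the first component while its group mates lay at -105 and -84.14.

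**Figure D1:**
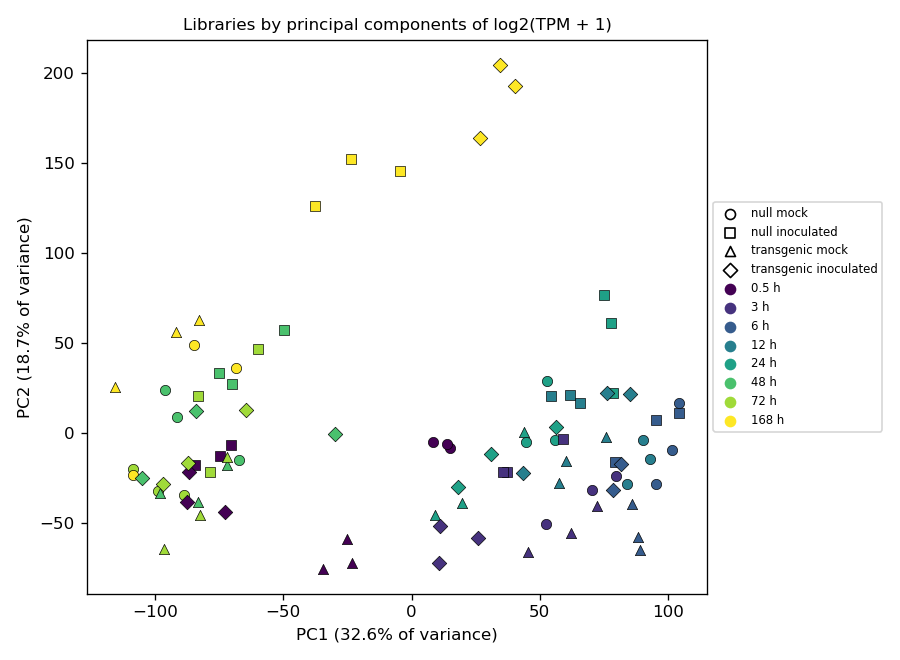
Each point is 1 of the 95 libraries, placed by the first (x axis, 32.6% of variance) and second (y axis, 18.7%) principal component of log2(TPM + 1), with genotype and treatment as the symbol and time as the colour. The inoculated libraries of 168 h lie at the top, and the inoculated libraries of 0.5 h lie at the left among those of 48 and 72 h.

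Inoculated null plants were compared with mock null plants to follow the response without the transgene. At 0.5 h, 3712 genes were higher and 4454 lower (limma, adjusted p threshold 0.05), and after median-ratio scaling, which turned the majority, 4696 were higher and 4378 lower. Zm00001d046234 fell from 496 ± 120 to 0.680 ± 0.11 TPM (SD, n = 3 each), a log2 change of -8.18 ± 0.69 (SE, limma adjusted p = 1.3e-14). It fell in transgenic plants as well, from 192 ± 77 to 0.671 ± 0.42 TPM, by -6.81 ± 0.69 (SE, limma adjusted p = 2.9e-11), and the difference between genotypes did not pass the test (1.38 ± 0.98, adjusted p = 0.64). Its level in mock plants was not constant. It fell there between 24 and 48 h, from 774 ± 110 to 1.78 ± 2.3 TPM in null mocks (SD, n = 3 each). In transgenic mocks it went from 789 ± 150 to 2.28 ± 1.7 TPM. At 168 h no mock library of either genotype exceeded 1.17 TPM. The fall at 0.5 h thus resembled a change that mock plants also showed.

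In null plants 1344 genes were higher and 406 lower at 3 h, 133 and 49 at 6 h, 1665 and 695 at 12 h, and 2110 and 1549 at 24 h. At 48 h 722 were higher and 337 lower, and at 72 h 1024 were higher and 140 lower. With median-ratio scaling the split became 855 higher and 679 lower at 3 h, 90 and 61 at 6 h, 918 and 1072 at 12 h, and 621 and 334 at 72 h, so that the majority of calls at 12 h changed direction. The median of all genes before scaling was 0.153 at 3 h, 0.119 at 12 h and 0.129 at 72 h on the log2 scale. A fit to the libraries of the same time alone called 1 gene at 6 h, 4127 at 12 h, 1485 at 24 h (712 higher and 773 lower), 18 at 48 h and 67 at 72 h. The counts also changed when 1 library was left out, which in itself leaves a smaller group and less power. The lowest counts were 696 at 3 h without inoculated replicate 2, and 49 at 6 h and 1008 at 12 h without inoculated replicate 1. They were 1697 at 24 h without inoculated replicate 3, 314 at 48 h without mock replicate 1 and 188 at 72 h without inoculated replicate 2.

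At 168 h 8371 genes were higher and 2174 lower in inoculated null plants. The median gene was 0.308 higher on the log2 scale, and after median-ratio scaling, which left a median of 0.0522, 4588 were higher and 3657 lower. The genes called higher held 18.2% ± 5.0 of the TPM in mock and 40.3% ± 5.0 in inoculated null plants (SD, n = 3 each), and those called lower held 39.0% ± 10 and 13.8% ± 3.6. The count was 5708 without replicate 2 of the mock group, in place of 10545, and 4525 from the libraries of 168 h alone. No other of the 6 libraries moved the count by over 1.5 times when left out, and the highest was 11045. Mock replicate 2 lay apart from its group mates, at -23.3 against 49.2 and 36.07 on the second component. Its 50 most abundant genes held 29.3% of the TPM, against 21.8% and 22.0% in theirs. The number of calls at 168 h thus depended on that library.

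Zm00001d031157 and Zm00001d036539 had the largest fitted rises, both at 168 h. Zm00001d031157 was at 710, 744 and 1870 TPM in inoculated null plants, where the mocks were at 0, 0.529 and 3.69 TPM (log2 change 9.02 ± 1.5 SE, limma adjusted p = 1.2e-06). In inoculated transgenic plants it was at 7990, 12200 and 12500 TPM and was listed at 0 in all 3 mocks, so no fold is given (limma adjusted p = 2.4e-12). The difference between genotypes did not pass the test (adjusted p = 0.089), and passed it in the fit to the libraries of 168 h alone (limma adjusted p = 0.0056, in a range of 0.0056 to 0.2 over the alternatives, the highest without null mock replicate 2). Zm00001d036539 rose to 763 ± 530 TPM from 6.75 ± 7.5 in null plants (6.80 ± 1.2 SE, limma adjusted p = 8.3e-06). In transgenic plants it reached 11200 ± 1500 TPM (SD, n = 3), with mock libraries at 0, 0 and 0.255 TPM, and its response differed between genotypes (6.54 ± 1.7 SE, limma adjusted p = 0.0018). The size of that difference depended on the pseudocount, at 9.03 with 0.1 TPM and 5.15 with 5 TPM. The order of the genotypes was not the same at earlier times. At 24 h inoculated null and transgenic plants were at 324 ± 260 and 96.8 ± 130 TPM for Zm00001d031157 (SD, n = 3 each). For Zm00001d036539 they were at 615 ± 370 and 54.3 ± 77 TPM. At 48 h the means were 182 and 18.6 TPM, and 555 and 151 TPM. At 12 h they went the other way, at 213 and 271 TPM, and 18 and 30 TPM. No test of these earlier differences is given.

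**Figure D2:**
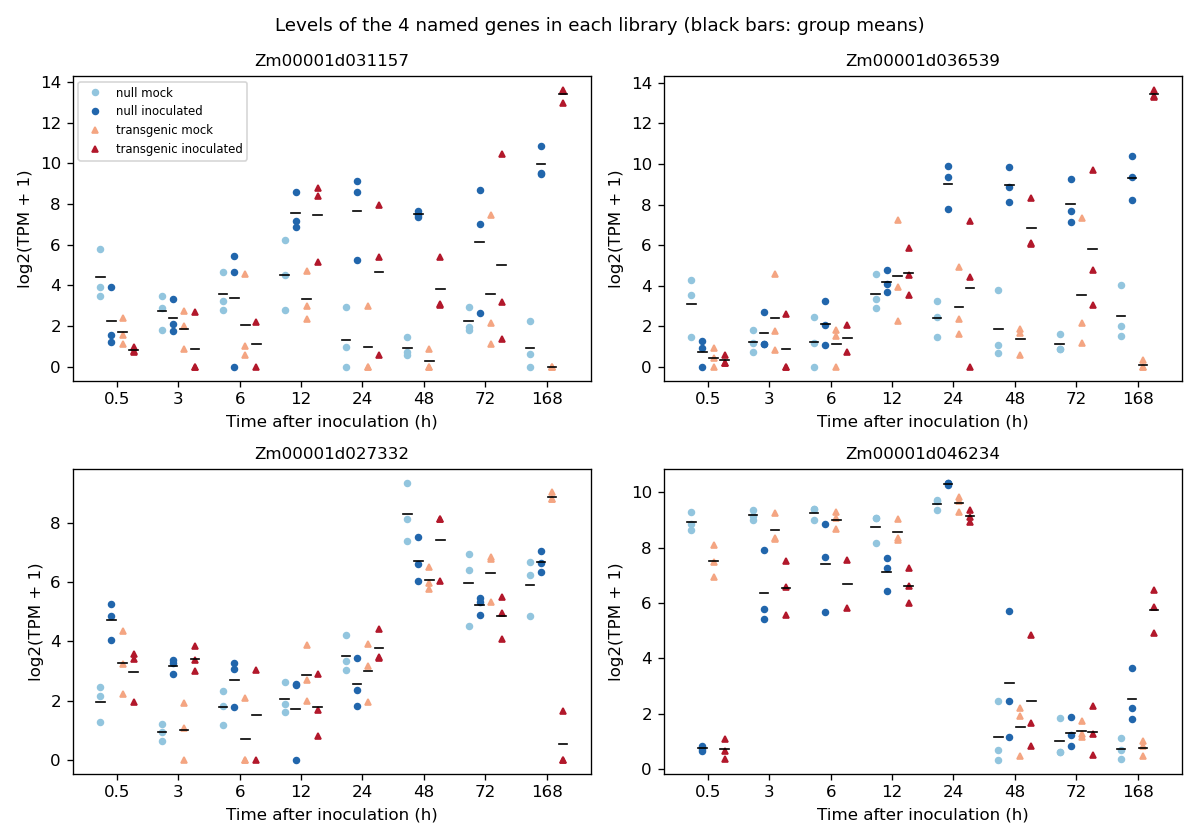
Level of each of the 4 named genes, as log2(TPM + 1) on the y axis, at each time after inoculation in h on the x axis, with 1 point per library and a black bar at each group mean. Zm00001d031157 and Zm00001d036539 are highest in inoculated transgenic plants at 168 h, Zm00001d027332 is near 0 there, and Zm00001d046234 is near 0 in inoculated plants at 0.5 h.

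Inoculated transgenic plants were compared with their own mocks in the same way. At 0.5 h 2946 genes were higher and 1701 lower, at 3 h 2035 and 1391, at 6 h 1101 and 348, at 12 h 302 and 126, and at 24 h 313 and 40. At 48 h 7 genes were higher and 1 lower, and at 72 h 1770 were higher and 432 lower. Libraries of 1 group differed widely at 72 h: Zm00001d031157 was at 1390, 8.13 and 1.54 TPM in inoculated replicates 1, 2 and 3 and at 1.19, 3.52 and 173 TPM in mock replicates 1, 2 and 3. Zm00001d036539 was at 829, 26.4 and 7.15 TPM and at 1.22, 3.44 and 162 TPM in the same libraries. The count at 72 h was 2448 without inoculated replicate 1 and 2216 without mock replicate 3. Scaling gave 706 higher and 715 lower at 6 h, 123 and 169 at 12 h, 226 and 74 at 24 h, and 1708 and 1386 at 72 h. The median of all genes before scaling was 0.153 at 6 h and 0.135 at 12 h. The libraries of the same time alone gave 669 genes at 12 h, 2 at 24 h and 4 at 72 h, and limma then called 0 at 48 h, where 1476 genes had an unadjusted p under 0.05. The count was 2968 at 0.5 h without inoculated replicate 3, 2264 at 3 h and 303 at 6 h without inoculated replicate 1, and 872 at 72 h without mock replicate 1. At 12 h it was 45 without inoculated replicate 3 (18 higher and 27 lower), 120 without mock replicate 2 (55 and 65) and 1087 without inoculated replicate 2, at 24 h 103 without mock replicate 2 and 547 without inoculated replicate 2, and at 48 h 1 without mock replicate 2 and 73 without inoculated replicate 1.

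At 168 h 6115 genes were higher and 7737 lower in inoculated transgenic plants, 54.0% of the genes tested. Scaling turned this majority, with 7260 higher and 7053 lower. The genes called higher rose from 12.2% ± 1.6 to 58.5% ± 6.2 of the TPM, and those called lower went from 63.5% ± 4.7 to 16.6% ± 4.6 (SD, n = 3 each). Zm00001d027332 was at 470 ± 47 TPM in mock plants and at 0, 0 and 2.12 TPM in inoculated ones (-8.33 ± 0.69 SE, limma adjusted p = 5.6e-17). In null plants it was at 67.3 ± 37 TPM in mock and 103 ± 26 TPM in inoculated plants (0.77 ± 0.69 SE, adjusted p = 0.39), and the responses differed (-9.09 ± 0.97 SE, limma adjusted p = 1.3e-11), by -11.5 with a pseudocount of 0.1 TPM and -7.11 with one of 5 TPM. Genes below 1 TPM in all 24 mock libraries of their genotype that reached a mean of 10 TPM numbered 75 in transgenic and 13 in null plants, with 1 gene in both sets.

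**Figure D3:**
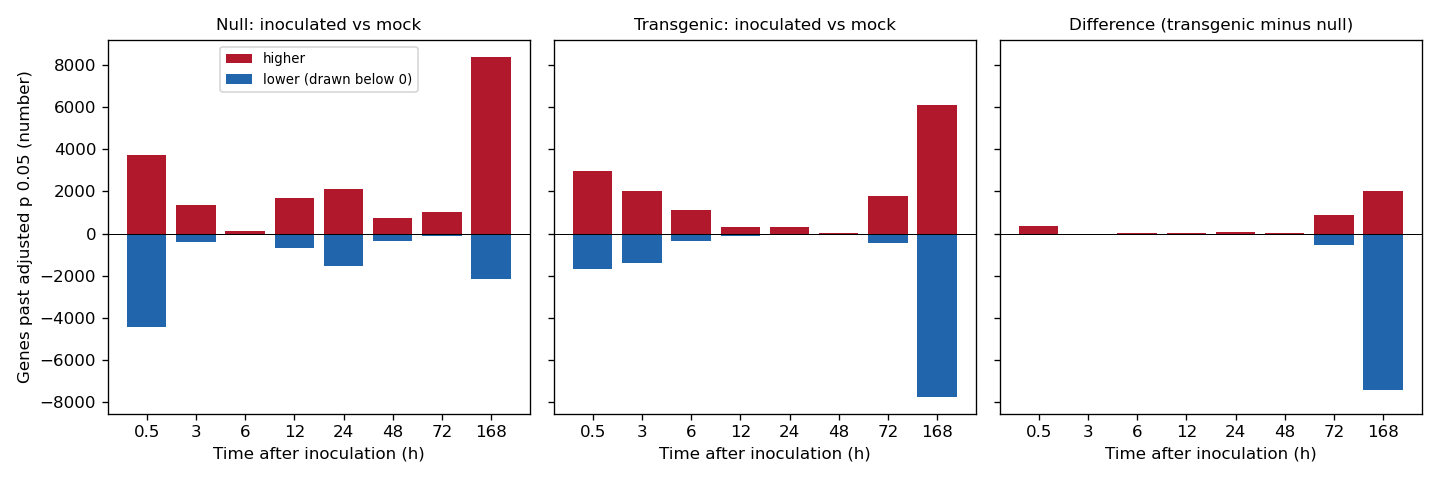
Number of genes past an adjusted p of 0.05 (y axis; red, higher; blue, lower, drawn below 0) at each time in h (x axis) for null plants, transgenic plants and the difference of their responses. The totals are largest at 168 h, with 10545 genes called in null and 13852 in transgenic plants. In null plants the bar of lower genes is tallest at 0.5 h, with 4454 genes against 2174 at 168 h.

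The responses of the genotypes, which share no libraries, overlapped more than independent lists would, in both directions, at each time except 72 h. At 0.5 h 2057 genes were higher in both and 1246 lower in both, where independent lists would share 426 and 295. At 3 h 789 were higher in both and 242 lower in both (107 and 22 for independent lists), at 6 h 70 and 32 (5.7 and 0.664), at 12 h 189 and 84 (19.6 and 3.41), at 24 h 141 and 24 (25.7 and 2.41) and at 48 h 5 and 1 (0.197 and 0.0131). At 168 h 4153 were higher in both and 1806 lower in both (1990 and 655 for independent lists), and 1045 went in opposite directions. The correlation of the log2 changes across genes, which are not independent replicates, was 0.68 at 0.5 and 168 h and between 0.42 and 0.62 from 3 to 48 h. At 72 h 59 genes were higher in both, where independent lists would share 70.6, 8 were lower in both (2.36), 23 went in opposite directions, and the correlation was 0.10.

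The difference in response between genotypes was tested as an interaction at each time. At 168 h 2033 genes had a higher and 7434 a lower response in transgenic plants, with a median shift of all genes of -0.369. Scaling left 3774 and 3975, and the libraries of 168 h alone gave 4181 genes. Of the 9467 genes, 3661 were called lower in transgenic plants with no call in null plants, and 1006 were called higher in null and lower in transgenic plants. Another 858 were called higher in transgenic plants with no call in null plants, and 1479 higher in null plants with no call in transgenic plants. After scaling these classes held, in the same order, 2321, 290, 1978 and 417 genes. Of 5959 genes called in the same direction in both genotypes, 74.8% had the larger change in transgenic plants, with a median absolute log2 change of 1.68 against 1.12, and 81.0% of 5937 had it after scaling. The share was also above 50% at 3 h, with 63.1% of 1031 genes (62.4% after scaling), and at 6 h, with 65.7% of 102 (63.3%). At 12 h it was 52.7% of 273 genes (53.2% after scaling) and at 24 h 55.2% of 165 (50.3%). Transgenic plants had fewer calls than null plants at 12 and 24 h, which selects larger changes in them among genes called in both. At 48 h only 6 genes were called in both, with a share of 50%. The share was lower at 0.5 h, with 40.2% of 3303 genes (39.0% after scaling), and at 72 h, with 25.4% of 67 genes (27.5% after scaling).

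**Figure D4:**
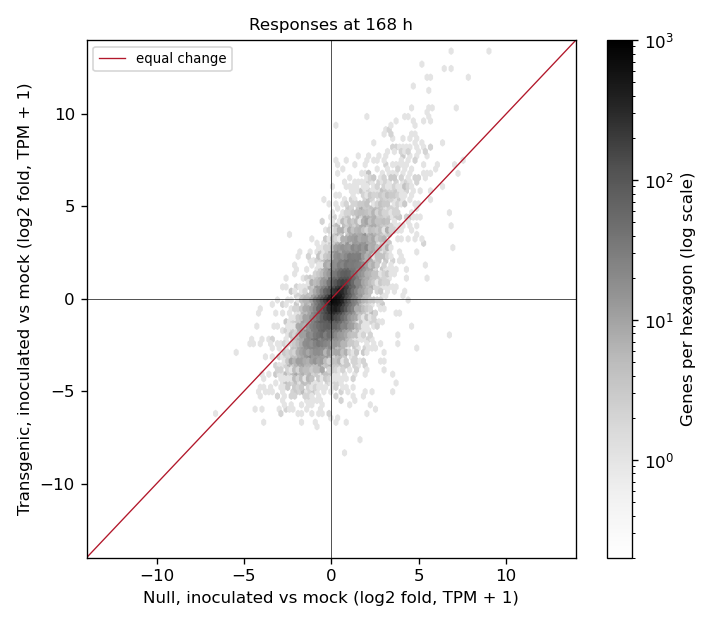
Log2 fold change of inoculated over mock plants at 168 h for the 25673 genes, null plants on the x axis and transgenic plants on the y axis, with darker hexagons holding more genes on a log scale. Among the 5959 genes called in the same direction in both, 74.8% had the larger change in transgenic plants, on the steeper side of the red line of equal change.

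At 72 h 898 genes had a higher and 533 a lower response in transgenic plants. The majority turned without 1 library, to 176 higher and 194 lower without replicate 1 of the inoculated null group and to 602 higher and 774 lower without replicate 1 of the transgenic mock group. The total of 1431 was 370 in the first case, 4 from the libraries of 72 h alone, and 2257 without replicate 1 of the inoculated transgenic group. Scaling gave 1432 higher and 940 lower. At 0.5 h 355 genes had a higher and 22 a lower response, and the total of 377 became 88 without replicate 2 of the transgenic mock group and 927 from the libraries of 0.5 h alone. The totals were 1 gene at 3 h (lower, with 2 higher and 1 lower after scaling and a median shift of -0.111 before it), 2 at 6 h, 47 at 12 h, 133 at 24 h (70 higher and 63 lower, 47 and 70 after scaling) and 32 at 48 h. The libraries of the same time alone called 0 genes with limma at 24 h, where 2436 had an unadjusted p under 0.05. Leaving out 1 library gave 12 to 119 genes at 12 h (without null mock replicate 2 and inoculated transgenic replicate 2), and 23 to 445 at 24 h (without inoculated null replicates 3 and 1). At 24 h the majority also turned, to 200 higher and 245 lower, without inoculated null replicate 1. At 48 h the range ended at 160 (without null mock replicate 3), and the split of 23 higher and 9 lower became 25 and 91 without inoculated null replicate 2.

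Transgenic and null plants were also compared within each treatment, averaged over the 8 times. In mock plants 980 genes were higher and 5423 lower in the transgenic genotype, and in inoculated plants 721 were higher and 6784 lower. After scaling these became 2404 and 3757 in mock and 1344 and 2043 in inoculated plants, where the median of all genes before scaling was -0.12. The 50 most abundant genes mostly held more of the TPM in transgenic plants, as with 32.2% ± 2.4 against 25.3% ± 0.56 in mocks of 0.5 h (SD, n = 3 each). The mean was not higher in transgenic plants at 12 h or in mocks of 168 h. Such a shift of shares lowers other genes, and its part in these counts was not tested beyond the scaling. Without replicate 2 of every group the totals were 2207 in place of 6403 and 1250 in place of 7505. In both treatments 250 genes were higher and 3006 lower (27.5 and 1430 for independent lists), and 515 and 1071 after scaling. Most of these differences were small, with a median absolute log2 difference of 0.38. A difference of 2-fold or more in both treatments was found for 41 higher and 109 lower genes, and for 66 of these 150 the sign was the same in all 16 combinations of time and treatment. The 150 became 385 with a pseudocount of 0.1 TPM and 39 with one of 5 TPM.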

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

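The interaction tests in this part were planned, and the exchanges of labels and the tests of the larger response at 168 h were chosen after the results were seen. A difference between the genotypes' responses was called for 377 genes at 0.5 h, 1 at 3 h, 2 at 6 h, 47 at 12 h, 133 at 24 h, 32 at 48 h, 1431 at 72 h and 9467 at 168 h. Exchanging genotype labels within each treatment gave, among 100 splits with the real one included, as many genes in 9 splits at 0.5 h, 62 at 3 h, 12 at 12 h, 21 at 24 h and 32 at 48 h, so chance was not excluded at these times. The highest other splits gave 2114, 3352, 212, 6888 and 1841 genes. Counts several times the real one point to a structure of the samples. The highest splits at 3, 24 and 48 h exchanged all 6 inoculated labels, that at 0.5 h exchanged 4 of them and that at 12 h all 6 mock labels, which turns the contrast toward the difference between the genotypes themselves. At 72 h 3 of 100 splits and at 168 h 2 of 100 gave as many genes, with other splits reaching 2519 and 9645. The split with 2519 genes exchanged all 6 mock and 4 inoculated labels, which up to sign exchanges 1 inoculated library of each genotype. The split with 9645 genes exchanged 4 mock and all 6 inoculated labels, which up to sign exchanges 1 mock library of each genotype. Both shares were under 0.05, so few exchanged splits called as many genes, with no adjustment for the number of times tested. Exchanged labels also bring the difference between the genotypes themselves into the contrast, so the splits are not a clean measure of chance. Without an adjustment for the times tested, these shares alone do not exclude chance for the interaction at 72 or 168 h. The 72 h count was 4 genes from the libraries of that time alone. At 168 h it was 4181 from the libraries of that time alone, and 7668 to 10171 when 1 library was left out. No split was drawn at 6 h, where 1 group held 2 libraries.

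Among the named genes, the responses at 168 h differed for Zm00001d036539 (6.54) and Zm00001d027332 (-9.09 on the log2 scale). Each rests on a transgenic group with 2 of 3 libraries listed at 0, so its size depended on the pseudocount: 9.03 and -11.5 with 0.1 TPM, 5.15 and -7.11 with 5 TPM.

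Among genes called in both genotypes, a larger change in transgenic plants was not particular to 168 h. Its share was also above 50% at 3 h (63.1%), 6 h (65.7%), 12 h (52.7%) and 24 h (55.2%, and 50.3% after scaling). It was not seen at 0.5 h (40.2%) or 72 h (25.4%). A gene called in both must also pass in the genotype with fewer calls, where the adjustment asks for a smaller p-value. This favours larger changes in that genotype. At 12 and 24 h it was the transgenic one, with 428 genes called against 2360 and 353 against 3659. The shares at 12 and 24 h therefore do not show a larger response of transgenic plants as a whole. The larger response of transgenic plants at 168 h may reflect the genotype, the stage of the plants or the tissue taken. Scaling of the libraries was not the whole cause by this test, since 81.0% of genes called in the same direction in both genotypes still had the larger change in transgenic plants after it. No one library carried it: the lowest share when each of the 12 libraries was left out was 66.2%. How far infection had advanced and which part of the plant was sampled were not tested, so a difference in stage or tissue stays open beside the transgene.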

How the results depend on the processing

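The pseudocounts and the scaling in this part were chosen after the results were seen, and the other alternatives were planned. No paired analysis was possible because the labels give no replicate numbers, and those used here follow accession order. No named gene changed sign, and only the difference for Zm00001d031157 at 168 h changed side of the threshold, with limma adjusted p from 0.0056 (libraries of 168 h alone) to 0.2 (without null mock replicate 2). The count models fixed in advance were not run, since TPM values are not counts. Depth is unknown. The counts at 0.5 and 3 h in null plants, at 0.5, 3, 6 and 168 h in transgenic plants and for the genotypes in mock plants stayed within 1.5 times under the filter, pseudocount, scaling and smaller-fit alternatives. For the others the cause was not tested. Without the low-value filter 44 genes were called at 48 h in transgenic plants, and differences became 6 at 3 h, 29 at 6 h and 54 at 48 h. With a pseudocount of 0.1 TPM null plants had 108 at 6 h and transgenic plants 266 at 12 h and 21 at 48 h, and differences were 141 at 0.5 h, 0 at 3 and 6 h (limma, 1906 and 1317 genes with an unadjusted p under 0.05), 20 at 12 h, 63 at 24 h and 13 at 48 h. With 5 TPM the counts were 297, 679 and 22, and differences 636 at 0.5 h, 10 at 3 h, 11 at 6 h, 248 at 24 h and 51 at 48 h. Median-ratio scaling gave 80 in transgenic plants at 48 h, differences of 3 at 3 h, 30 at 12 h and 2372 at 72 h, and 3387 for the genotypes in inoculated plants.

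Fits to the libraries of 1 time gave 1 gene at 6 h, 4127 at 12 h, 1485 at 24 h, 18 at 48 h, 67 at 72 h and 4525 at 168 h in null plants, and 669 at 12 h, 2 at 24 h, 0 at 48 h and 4 at 72 h in transgenic plants. Differences were 927 at 0.5 h, 0 at 3 h, 4 at 12 h, 0 at 24 h, 0 at 48 h, 4 at 72 h and 4181 at 168 h. Genes with an unadjusted p under 0.05 in limma numbered 1476 for the 0 in transgenic plants, and 2378, 2436 and 1218 for the differences at 3, 24 and 48 h. In null plants the fits to 1 time raised the count from 8166 to 9885 at 0.5 h and from 2360 to 4127 at 12 h. Fewer residual degrees of freedom alone would not raise a count, so the spread seems unequal over the times. Where counts fell, as at 48 and 72 h, p-values from all 95 libraries may be too small.

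Leaving out 1 library moved 105 of 190 counts by over 1.5 times, 77 downward and 28 upward, and an arm left with 1 library was assumed to vary like the other groups. In null plants (main count first) these were 1750 at 3 h without inoculated 1 (799), inoculated 2 (696), mock 1 (860) or mock 3 (1149), with 1606 the highest; 182 at 6 h without inoculated 1 (49), inoculated 2 (57), mock 2 (88) or mock 3 (74), highest 271; 2360 at 12 h without inoculated 1 (1008), mock 2 (1050) or mock 3 (1326), highest 1832. At 24 h 3659 became 2367 and 1697 without inoculated 2 and 3, highest 4122, and at 48 h 1059 became 438 without inoculated 2 and 314 without mock 1, highest 1068. At 72 h 1164 became 1788 and 188 without inoculated 1 and 2, and 523, 465 and 615 without mock 1, 2 and 3. At 168 h 10545 became 5708 without mock 2, highest 11045. Leaving out a library also leaves a smaller group and less power, so a fall alone does not mark that library as unusual. Mock 2 at 168 h, however, also lay apart from its group mates on the second principal component.

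In transgenic plants 4647 at 0.5 h became 3087 and 2968 without inoculated 2 and 3, highest 4709, and 3426 at 3 h became 2264 without inoculated 1, highest 3205. At 6 h 1449 became 303 and 391 without inoculated 1 and 2, and 554 and 577 without mock 1 and 2, highest 2094. At 12 h 428 became 143, 1087 and 45 without inoculated 1, 2 and 3, and 200, 120 and 247 without mock 1, 2 and 3. At 24 h 353 became 156, 547 and 150 without inoculated 1, 2 and 3, and 103 without mock 2. At 48 h 8 became 73 and 61 without inoculated 1 and 2, and 50, 1 and 5 without mock 1, 2 and 3. At 72 h 2202 became 1287 and 1136 without inoculated 2 and 3, and 872 and 1375 without mock 1 and 2, highest 2448.

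For the difference, 377 at 0.5 h became 171 and 237 without inoculated null 1 and 2, 145 without inoculated transgenic 3, 239, 226 and 140 without mock null 1, 2 and 3, and 88 without mock transgenic 2, highest 356. The 1 at 3 h became 3 and 0 without inoculated null 1 and 3, 11, 0 and 4 without inoculated transgenic 1, 2 and 3, 3 without mock null 2, and 3, 19 and 3 without mock transgenic 1, 2 and 3 (for both 0 counts limma gave 1225 and 1224 genes with an unadjusted p under 0.05). The 2 at 6 h became 7 without inoculated null 1, 12 and 4 without inoculated transgenic 1 and 2, 1 and 1 without mock null 1 and 2, and 1 and 13 without mock transgenic 1 and 3. The 47 at 12 h became 23, 27 and 25 without inoculated null 1, 2 and 3, 14, 119 and 25 without inoculated transgenic 1, 2 and 3, 31, 12 and 18 without mock null 1, 2 and 3, and 18 and 16 without mock transgenic 1 and 2. The 133 at 24 h became 445, 52 and 23 without inoculated null 1, 2 and 3, 51, 42 and 223 without inoculated transgenic 1, 2 and 3, 216 and 72 without mock null 1 and 2, and 205 and 70 without mock transgenic 1 and 2. The 32 at 48 h became 116 without inoculated null 2, 63, 10 and 63 without inoculated transgenic 1, 2 and 3, 10, 20 and 160 without mock null 1, 2 and 3, and 105, 16 and 16 without mock transgenic 1, 2 and 3. The 1431 at 72 h became 370 without inoculated null 1, 2257 and 502 without inoculated transgenic 1 and 3, and 569 without mock null 2. At 168 h no library moved 9467 by that much. The genotype counts of 6403 in mock and 7505 in inoculated plants became 2207 and 1250 without replicate 2 of every group, with highest values of 5306 and 8378.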

Other observations

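The contrasts between treatments and between genotypes in this part were planned, and the comparison of mock plants over time, the 2-fold gene set, the tests on it and on the 0.5 h response, and the exchanges of labels were chosen after the results were seen. Mock plants alone changed widely between 24 and 48 h. In null mocks 4249 genes were higher and 6236 lower at 48 h than at 24 h (limma, adjusted p threshold 0.05), and in transgenic mocks 3535 were higher and 4181 lower. After scaling the splits were 5773 and 4845, and 4821 and 3734. Both genotypes shared 2530 higher and 3344 lower genes (585 and 1020 for independent lists), with a correlation across genes of 0.83. The 10 splits of each set of 6 libraries are too few for a share under 0.05: the real counts were 10485 and 7716, reached by 1 split each, and the highest others 1806 and 100.

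The response at 0.5 h resembled that change of mock plants. Across genes its correlation with the 48 h against 24 h difference of the mocks, from other libraries, was 0.71 in null and 0.50 in transgenic plants. Of the inoculated libraries of 0.5 h, 6 of 6 were closest to a mock group of 48, 72 or 168 h. A candidate explanation is a difference in plant state or sampling hour that mock plants also pass through, and a rapid response to the inoculum or its handling stays open, since the labels give no clock times. The stated times of 24, 48, 72 and 168 h lie whole days apart. If all plants were treated at the same hour, a change of hour between these mocks would need sampling off that schedule. Whether the inoculated or the mock plants of 0.5 h were out of step cannot be told. Scaling of the libraries does not account for it, by this test, with 9074 genes called in null plants after it.

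Of the 150 genes that differed 2-fold or more between genotypes in both treatments, a minority lay near another in ID order, but more than in random orders. For 47 of the 150 another lay within 10 tested IDs on either side, where 10000 random orders gave a mean of 16.6 and at most 37 (p = 1e-04, the smallest these permutations can give). The rest had no such neighbour. If ID order follows position, which was not checked here, linked segments that differ between the 2 genotypes may contribute, whether from the parents or from alleles that match the reference transcripts less well. These could not be separated here. No other list of called genes was set against random orders. The test therefore cannot tell whether such nearness is particular to differences between the genotypes. After median-ratio scaling 110 of the 150 were still 2-fold or more in both treatments.

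For the responses of each genotype, 3 libraries against 3 allow 10 splits, too few for a share under 0.05. Except at 48 h in transgenic plants, the real split gave the highest count, reached by 1 split, in each response tested. The 6 h response of transgenic plants was not split. In null plants the highest other split gave 65 genes at 0.5 h, 5 at 3 h, 12 at 6 h, 3 at 12 h, 827 at 24 h, 98 at 48 h, 71 at 72 h and 2490 at 168 h. In transgenic plants it gave 37 at 0.5 h, 85 at 3 h, 277 at 12 h, 180 at 24 h, 27 at 72 h and 4455 at 168 h. At 48 h in transgenic plants 5 of 10 splits gave 8 genes or more, and one gave 1430. For the genotype contrasts averaged over times, only the real 1 of 100 splits gave 6403 genes in mock and 7505 in inoculated plants, with highest others of 628 and 3323, so a chance exchange of labels was excluded there. This does not test whether libraries with the same replicate number share a factor, and without number 2 the counts were 2207 and 1250.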
